A study of Gallus gallus with 28 samples.

How the data were processed

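Total RNA from small intestine of male chick embryos and chicks was measured on 28 arrays, 4 at each of 7 ages. Per the labels, RNA came from intestinal segments of 6 birds per age, was extracted with a column kit and was labelled with biotin; the tissue label reads whole intestine, while the design text names the small intestine. The design text names 2 lines of birds and 2 pools, and neither is given per array, so line and pool were not terms in any fit. Replicate numbers follow the order of the sample records, and the labels pair no arrays across ages. No arrays were averaged: 0 pairs of arrays held identical values, and the largest correlation between 2 arrays was 0.997 (across probe sets, which are not independent replicates).

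The deposited values are one intensity per probe set and array on a linear scale. Per the submitters' processing notes they were made with GCRMA, which corrects background by probe sequence and summarises the probes of a set; the version and whether all arrays were processed together are not given in the sources used here. Scanner files and detection calls were not used here. The table holds 38535 probe sets. Control and reporter probe sets, 153 in number, were left out, 10 of which carry a gene in the annotation. Of the others 27168 had 1 gene symbol and were used, 177 had several and 11037 had no gene listed, and none of these was named. Gene IDs of 26863 of the 27178 probe sets with 1 symbol were in the RefSeq gene table, and 0 symbols changed through it. Here log2 was taken, and each of the 13009 symbols was represented by its probe set with the highest mean over the 28 arrays (7334 symbols had more than 1). Genes were kept with a log2 value over 4 in at least 4 arrays, which left 8396 and removed 4613, among them 129 of 295 solute carriers. Of the 6189 genes called between e18 and d14, 96 had another probe set called the other way, as did 3 of the 129 called solute carriers and 0 of the 165 genes that the naming rule selected. Only 64 of these 165 had more than 1 probe set over the filter and could show such a difference. GCRMA gives low probe sets nearly constant values, so changes of weakly expressed genes can be understated or bounded only.

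Background was set per array at the 95th percentile of the 541 probe sets with IDs beginning NC-, which lay between 2.97 and 3.54 on the log2 scale. Where the mean of one age was at or below its background, the fold is given as at least N-fold against that background, and no fold is given where both ages were below it. For after against before hatch each age of the lower side below its background entered at that background. Within an age the correlation between arrays lay between 0.978 and 0.994 across genes.

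One mean per age was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, 21 residual and 3.13 prior degrees of freedom). The moderated F-test on 6 degrees of freedom compared all ages; contrasts compared d14 with e18, the mean of d1, d3, d7 and d14 with that of e18 and e20, and each pair of consecutive ages. All limma tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes tested, and genes under 0.05 were called. Solute carriers were all symbols beginning with SLC or SLCO and a number. Among them SLC4A1AP, SLC7A6OS, SLC9A3R1 and SLC9A3R2 carry the prefix but encode no carrier; without these 4, added after seeing the data, 126 solute carriers were called between e18 and d14. Counts for solute carriers and lists are also given adjusted over the list alone. The share called and the share higher among called genes were compared with those of other genes by Fisher's exact test, adjusted over 9 and 7 tests. This test takes genes as independent, so its p-values are too small where genes move together across the arrays.

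Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists with at least 5 genes tested, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. In all 33 lists were written: the solute carriers as a whole; carriers of amino acids, of peptides and sugars, of metals, phosphate and sulfate, of ions and acid-base equivalents, of vitamins, nucleosides and nucleotide sugars, of organic anions, cations, bile acids, monocarboxylates and fatty acids, mitochondrial carriers, and neurotransmitter and vesicular carriers; brush border hydrolases, enterocyte cytoskeleton and junctions, lipid absorption, fatty acid oxidation and ketogenesis, cholesterol synthesis, glycolysis and fructose metabolism, the respiratory chain, ribosomal proteins, DNA replication and mitosis, crypt genes; markers of goblet cells, enteroendocrine cells, smooth muscle, fibroblasts and matrix, erythroid cells, T cells, B cells, macrophages and heterophils, antigen presentation and interferon response, enteric neurons and glia, endothelium, exocrine pancreas, liver and yolk sac; and xenobiotic metabolism.

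The design, the lists, the naming rule and the alternatives not said to be chosen after seeing the data were fixed before the data were examined. The rule named, for d14 against e18, the 12 solute carriers with the largest rises and the 8 with the largest falls, and the 8 largest rises and 8 largest falls over all genes, each called and with all 4 arrays of one age above all 4 of the other; up to 4 called members of each list with the largest change; for each other contrast the 3 largest rises, the 3 largest falls and the 3 solute carriers with the largest change; and always SLC15A1, SLC5A1, SLC2A2, SLC2A5, SLC6A19, SLC7A9, SLC3A1, ANPEP and SI. Named outside the rule, after their values were seen, were CPM, MVK, TFRC, AMY1A, PLA2G1B, AMY2A, INS, AvBD7 and the values of rule genes in other steps.

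The steps were tested on simulated data for the contrast of d14 with e18 over the 8396 genes: of 100 genes changed by 0.5 on the log2 scale 39 were called, and of 100 changed by 1, 89 were called, all with the right sign, and 6 unchanged genes were called. The simulated noise was normal and independent between genes and arrays, and only the d14 values of these genes were changed. The measured arrays share differences across genes and have far more genes called, so these rates need not hold for them. Alternatives were no filter, a filter at log2 over 6, values under 4 raised to 4, the mean over the probe sets of a gene, quantile normalization, arrays centred on the median, eBayes with trend and robust settings, array weights, a minimum change of 1 on the log2 scale, only the arrays of the ages compared, and each array left out in turn. After seeing the data, e20 in place of e18, all arrays without e18 and the family without the 4 other symbols were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.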

Results

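Gene expression was measured in total RNA from the small intestine of male chick embryos and chicks on 28 Affymetrix chicken arrays. The arrays covered 7 ages with 4 arrays each: embryonic days 18 and 20 (e18 and e20), hatch itself, and 1, 3, 7 and 14 days after it (d1, d3, d7 and d14). Around hatch a chick changes from yolk to feed, and absorption by the intestine takes over nutrient supply. The series is about the solute carrier (SLC) genes, which encode membrane carriers of sugars, amino acids, peptides, nucleosides, bile acids and ions. Values are log2 intensities, and the median intensity per array lay between 7.39 and 8.00 and the highest between 37275 and 49230. The labels name 2 lines of birds and 2 pools without assigning them to arrays, so p-values measure only the spread between arrays, which includes lines and pools and may be partly technical. The number of arrays limits the precision. Of 13009 named genes, 8396 passed the filter on low values and were tested, among them 166 of 295 solute carriers.

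Most of the transcripts tested, solute carriers included, differed between ages. Limma's moderated F-test called 7561 of the 8396 genes and 151 of the 166 solute carriers, and 151 when adjusted over the list alone. Of these 151 solute carriers, 91 had their lowest mean at e18 and 22 at d14. The highest mean fell at e18 for 23, at e20 for 14, at hatch for 23, at d1 for 34, at d3 for 21, at d7 for 12 and at d14 for 24. With the e18 arrays left out, an alternative chosen after seeing the data, 6860 genes and 137 solute carriers were called, and 25 solute carriers had their highest mean at e20.

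The first comparison set d14 against e18, the ends of the age series. Several single carriers known from the brush border rose between them. SLC5A1 (gene ID 395496), the sodium-glucose cotransporter of the brush border, rose from 7.73 ± 0.21 to 12.68 ± 0.11 (SD, n = 4 arrays), a change of 4.95 ± 0.12 (SE, limma adjusted p = 1.23e-20). SLC15A1 (gene ID 378789), the intestinal peptide transporter, rose by 4.09 ± 0.19 to a mean of 14.27, and SLC6A19 (gene ID 420971), a brush border carrier of neutral amino acids, by 5.33 ± 0.28. The fructose carrier SLC2A5 rose by 4.55 ± 0.26 and SLC2A2, which passes glucose to the blood side, by 4.42 ± 0.31. The nucleoside transporter SLC28A2 (gene ID 415338) rose 90.6-fold (adjusted p = 1.37e-21).

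Bile acid, ion and metal carriers were also among the large rises. SLC10A2 (gene ID 428018), the apical bile acid transporter, was not above background at e18 and was at least 67.2-fold higher at d14, and SLC51B, a subunit of the basolateral exporter of bile acids, at least 21.8-fold higher. The sodium-proton exchanger SLC9A2 rose by 5.93 ± 0.19, the anion exchanger SLC26A6 by 5.31 ± 0.32 and the manganese exporter SLC30A10 by 4.53 ± 0.34. The Golgi carrier SLC35A3 rose by 4.45 ± 0.25, and the monocarboxylate carrier SLC5A12 was at least 22.7-fold higher. SLC3A1 and SLC7A9, whose products together carry cystine and dibasic amino acids, rose by 3.01 ± 0.14 and 2.56 ± 0.20.

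Fewer solute carriers fell. SLC22A13 (gene ID 420423), an organic anion transporter, changed by −4.11 ± 0.36 (adjusted p = 1.59e-10). The vesicular acetylcholine transporter SLC18A3 was at least 9.00-fold lower at d14, the amino acid carrier SLC6A15 at least 6.38-fold and SLC16A12 at least 5.97-fold. SLC35F1 changed by −3.48 ± 0.24 and SLC35G2 by −3.18 ± 0.18. The cationic amino acid carrier SLC7A3 changed by −2.10 ± 0.35, with 1 of its d14 arrays at 3.92 and the others at 5.63 or above, and the nucleoside carrier SLC29A1 by −1.59 ± 0.19.

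**Figure D1:**
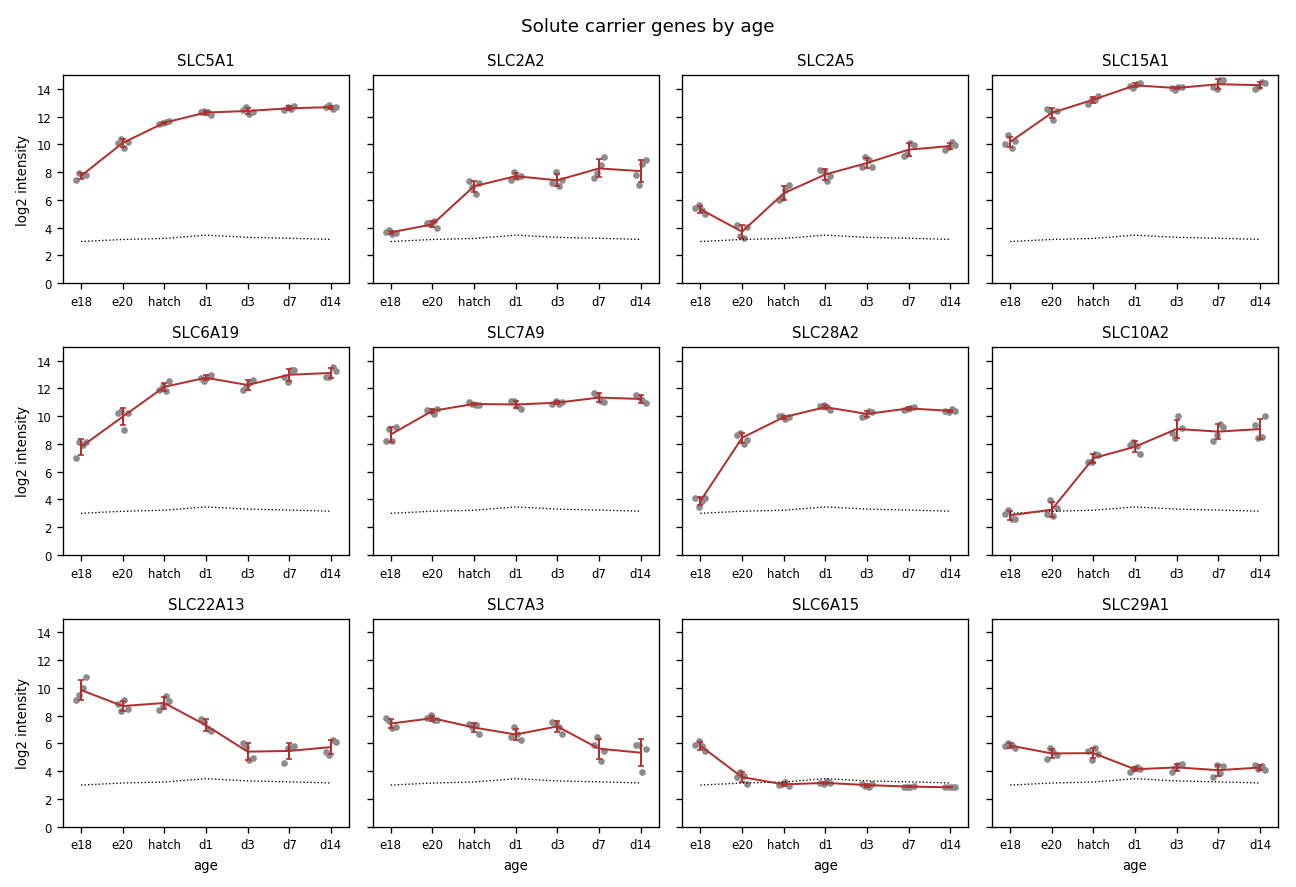
Log2 intensity (y axis) of 12 solute carrier genes at 7 ages (x axis). Grey points are single arrays, the red line joins the means of 4 arrays with bars of 1 SD, and the dotted line is the background level of the age. SLC5A1 rises from 7.73 at e18 to 12.68 at d14, and SLC22A13 goes from 9.85 to 5.74.

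In all, 129 of the 166 solute carriers were called between e18 and d14, 97 higher and 32 lower at d14 (130 adjusted over the list alone). Over all genes 6189 were called, 2788 higher and 3401 lower. Of the called solute carriers 75.2% were higher at d14, against 44.4% of the other called genes (Fisher's exact test, two-sided, adjusted p = 9.01e-12 over 7 tests). Here and in the other comparisons Fisher's test takes genes as independent, and its p-values overstate the evidence where carriers move together. The RNA came from tissue with several cell types, so none of these shares tells changes within cells from changes in the mix of cells. The share called, 77.7%, was close to the 73.6% of other genes (adjusted p = 0.507 over 9 tests). The e18 arrays also held high levels of pancreas and granule transcripts, with a mean of 10.15 over the exocrine pancreas list against 3.44 at e20. With e20 in place of e18, an alternative chosen after seeing the data, 5679 genes (2287 higher, 3392 lower) and 108 solute carriers (69 higher, 39 lower) were called.

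Each fixed sublist of carriers had a higher mean at d14 than at e18, and some were called against the other genes. Against e20 this did not hold for every sublist. Mitochondrial carriers had means of 8.64 at e20 and 8.54 at d14, and neurotransmitter and vesicular carriers 6.49 and 6.36. The means of the other sublists were higher at d14 than at e20. The sublists were not tested against each other. Of 24 carriers of organic anions, cations, bile acids, monocarboxylates and fatty acids, 18 rose and 2 fell (limma camera, adjusted p = 0.000125). Among 22 ion and acid-base carriers 16 rose and 3 fell (adjusted p = 0.00161), including SLC26A3, a chloride-bicarbonate exchanger, by 3.28 ± 0.35, and SLC9A3, at least 9.87-fold. Among 19 carriers of metals, phosphate and sulfate 12 rose and 1 fell (adjusted p = 0.00021), with SLC13A1 at least 9.03-fold and SLC41A2 6.18-fold higher. These lists and the family as a whole (adjusted p = 3.00e-06) passed with an estimated correlation as well.

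Of 18 amino acid carriers 10 rose and 5 fell (adjusted p = 0.0421), and the list did not pass with an estimated correlation (adjusted p = 0.221 with an estimated correlation) nor with e20 in place of e18 (adjusted p = 0.231). SLC36A1, a proton-coupled amino acid carrier, rose by 3.62 ± 0.23 and SLC43A2 by 3.13 ± 0.22. The other sublists were not called. Of 13 peptide and sugar carriers 6 rose and 4 fell (adjusted p = 0.105; 11 called adjusted over the list alone). Of 30 carriers of vitamins, nucleosides and nucleotide sugars 14 rose and 7 fell (adjusted p = 0.0774), of 24 mitochondrial carriers 11 rose and 7 fell (adjusted p = 0.166), and of 8 neurotransmitter and vesicular carriers 5 rose and 2 fell (adjusted p = 0.113). SLC25A22, a mitochondrial glutamate carrier, rose by 2.77 ± 0.16, and the creatine carrier SLC6A8 by 2.23 ± 0.17.

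Digestive enzymes and lipid-handling genes rose with the carriers. APOA4 (gene ID 395780), an apolipoprotein of the particles in which absorbed fat is exported, rose by 10.33 ± 0.22. FABP1, a fatty acid binding protein, rose by 5.97 ± 0.50, APOB by 6.02 ± 0.26 and the lipid receptor SCARB1 by 6.67 ± 0.37. Of 19 lipid absorption genes 17 rose and 0 fell (adjusted p = 3.25e-09, 17 adjusted over the list alone), a call that held with an estimated correlation. Of 17 brush border hydrolases 16 rose, DPP4 by 6.83 ± 0.22, the disaccharidase MGAM by 6.54 ± 0.18, ANPEP by 2.62 ± 0.12 and sucrase-isomaltase (SI) by 2.59 ± 0.12, while the carboxypeptidase CPM fell by 2.16. That list had an adjusted p of 2.59e-07 and an adjusted p = 0.0776 with an estimated correlation. Of 22 genes of the enterocyte cytoskeleton and junctions 18 rose and 3 fell (adjusted p = 4.38e-05), with the microvillus cadherin CDHR2 up by 6.14 ± 0.22 and the claudin CLDN1 changed by −3.59 ± 0.22, and the call held with an estimated correlation.

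Metabolic genes changed as well. Of 14 cholesterol synthesis genes 13 rose, among them INSIG1 by 4.62 ± 0.20 and MSMO1 by 3.93 ± 0.22, and MVK fell by 1.13 (adjusted p = 4.38e-05, and adjusted p = 0.168 with an estimated correlation). Of 16 fatty acid oxidation and ketogenesis genes 12 rose and 1 fell (adjusted p = 0.00161, and adjusted p = 0.156 with an estimated correlation), with EHHADH up by 3.83 ± 0.16. Of 27 xenobiotic metabolism genes 22 rose and 3 fell (adjusted p = 7.61e-06, and adjusted p = 0.0729 with an estimated correlation), with the efflux pump ABCB1 up by 4.88 ± 0.26. Of 15 glycolysis and fructose genes 8 rose and 6 fell (adjusted p = 0.311), and ketohexokinase (KHK), the first enzyme of fructose breakdown, was at least 29.9-fold higher. Of 62 respiratory chain genes 32 rose and 5 fell, 31 and 2 adjusted over the list alone (adjusted p = 0.00174, and adjusted p = 0.408 with an estimated correlation). For this list the respiratory chain median of 0.25 turned to −0.27 with e20 in place of e18 (adjusted p = 0.0471), and NDUFA4 changed by −1.38 ± 0.10.

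T cell, B cell and antigen presentation genes rose. GZMA (gene ID 395108), a granule protease of cytotoxic lymphocytes, was at least 509-fold higher at d14 and CD3E, a chain of the T cell receptor complex, rose by 4.87 ± 0.22. Of 10 T cell markers 9 rose and 0 fell (adjusted p = 7.96e-06), which held with an estimated correlation. Of 5 B cell markers 4 rose and 1 fell (adjusted p = 0.0044, and adjusted p = 0.0729 with an estimated correlation). Those that rose were IGLL1, by 8.89 ± 0.27, the immunoglobulin joining chain JCHAIN, at least 323-fold, BTK, by 1.88 ± 0.17, and PIGR, by 8.49 ± 0.34, which is the immunoglobulin receptor of epithelial cells. All 20 antigen presentation and interferon genes rose (adjusted p = 3.25e-09, and adjusted p = 0.0776 with an estimated correlation), with the class I molecule BF2 up by 5.91 ± 0.49. Of 13 macrophage and heterophil markers 7 rose and 1 fell (adjusted p = 0.0774). C1QA rose by 3.35 ± 0.30, and the cathelicidin CATH1, an antimicrobial peptide, was at least 301-fold lower. With e20 in place of e18 the macrophage and heterophil list was called as higher at d14 (adjusted p = 5.33e-06).

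Most goblet cell markers rose. CLCA1 (gene ID 424523), a secreted protein of goblet cells, was at least 2935-fold higher at d14, and FCGBP, a mucus protein, rose by 9.40 ± 0.16. Of 6 goblet cell markers 5 rose and TFF3 changed by −2.29 ± 0.65 (adjusted p = 0.00694, and adjusted p = 0.0811 with an estimated correlation). The calcium-binding protein CALB1 was at least 549-fold higher, and GATD3AL2 rose by 10.05 ± 0.46. Of 12 enteroendocrine markers 4 rose and 3 fell (adjusted p = 0.704), with cholecystokinin (CCK) up by 2.71 ± 0.24 and SCG3 changed by −2.58 ± 0.18. Of 15 crypt genes 3 rose and 12 fell (adjusted p = 0.113), with OLFM4 up by 3.27 ± 0.16 and TNFRSF19 changed by −3.31 ± 0.19.

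Genes of growth, stroma and nerves fell. COL14A1 (gene ID 396276), a fibril-associated collagen, changed by −8.41 ± 0.22, and all 22 fibroblast and matrix genes fell (adjusted p = 3.69e-09, and adjusted p = 0.0811 with an estimated correlation). Of 46 DNA replication and mitosis genes 41 fell and 0 rose, 42 adjusted over the list alone (adjusted p = 3.25e-09, and adjusted p = 0.138 with an estimated correlation), with the replicative helicase subunit MCM2 at −2.62 ± 0.17. Of 60 ribosomal protein genes 57 fell, 58 adjusted over the list alone, with a median of −0.66, and RPS27L rose by 1.79 ± 0.08 (adjusted p = 5.14e-10, and adjusted p = 0.168 with an estimated correlation). Of 17 neuron and glia markers 15 fell and 1 rose (adjusted p = 0.000295, and adjusted p = 0.0811 with an estimated correlation), with STMN2 at −4.00 ± 0.21. Of 16 smooth muscle markers 13 fell and 1 rose (adjusted p = 0.00675, and adjusted p = 0.377 with an estimated correlation). Of 13 endothelial markers 9 fell and 1 rose (adjusted p = 0.0143, and adjusted p = 0.171 with an estimated correlation), with CDH5 at −2.07 ± 0.13, and the list was not called with e20 in place of e18 (adjusted p = 0.239). KRT24, a keratin, was at least 755-fold lower at d14.

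Exocrine pancreas markers as a list were high at e18. Of 10 exocrine pancreas markers 8 fell and 0 rose (adjusted p = 0.00694, and adjusted p = 0.269 with an estimated correlation), among them the chymotrypsin CTRC, at −9.77 ± 1.32, and CPB1, at −8.31 ± 0.80, with 1 of the d14 arrays of CPB1 at 7.29 and the others at 2.87 or below. AMY1A and PLA2G1B changed by −0.29 and 1.21 and were not called. With e20 in place of e18 the median change of the exocrine pancreas list turned positive, at 1.22, and the list was not called (limma camera, adjusted p = 0.166). The zymogen granule protein SYCN changed by −10.08 ± 0.46, the defensin AvBD1 by −8.48 ± 0.22 and LECT2 by −8.45 ± 0.42, and C6orf58 was at least 390-fold lower. Of 8 liver and yolk sac genes 2 rose and 3 fell, 2 and 2 adjusted over the list alone (adjusted p = 0.704), and the sign of the median differed from that of the mean of 0.06 and of the test. Of the erythroid list 4 genes were tested, too few for a list test: the globins HBA1 and HBAD changed by −1.99 ± 0.36 and −2.80 ± 0.38, CA2 by 0.79 ± 0.21, and TFRC, at 0.26, was not called.

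**Figure D2:**
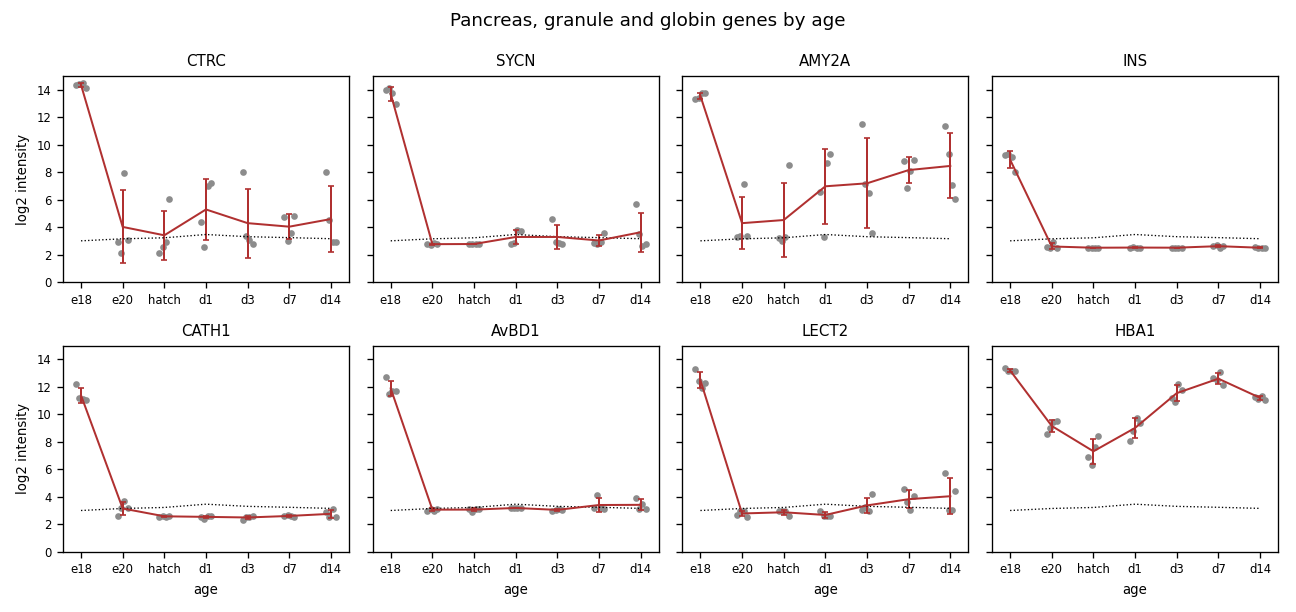
Log2 intensity (y axis) of pancreas genes (CTRC, SYCN, AMY2A, INS), granule and secreted defence genes (CATH1, AvBD1, LECT2) and a globin (HBA1) at 7 ages (x axis). Grey points are single arrays, the red line joins the means of 4 arrays with bars of 1 SD, and the dotted line is the background level of the age. CTRC has a mean of 14.35 at e18 and 4.01 at e20.

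Of the 32 lists tested between e18 and d14, 23 were called, 16 up and 7 down, and 7 were called with an estimated correlation. Of the 32, 26 had the same number of called members when adjusted over the list alone, and the largest difference was 4. With e20 in place of e18, 21 lists were called, and 3 of the 35 splits of the e18 and d14 arrays, the real one included, gave as many as 23.

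**Figure D3:**
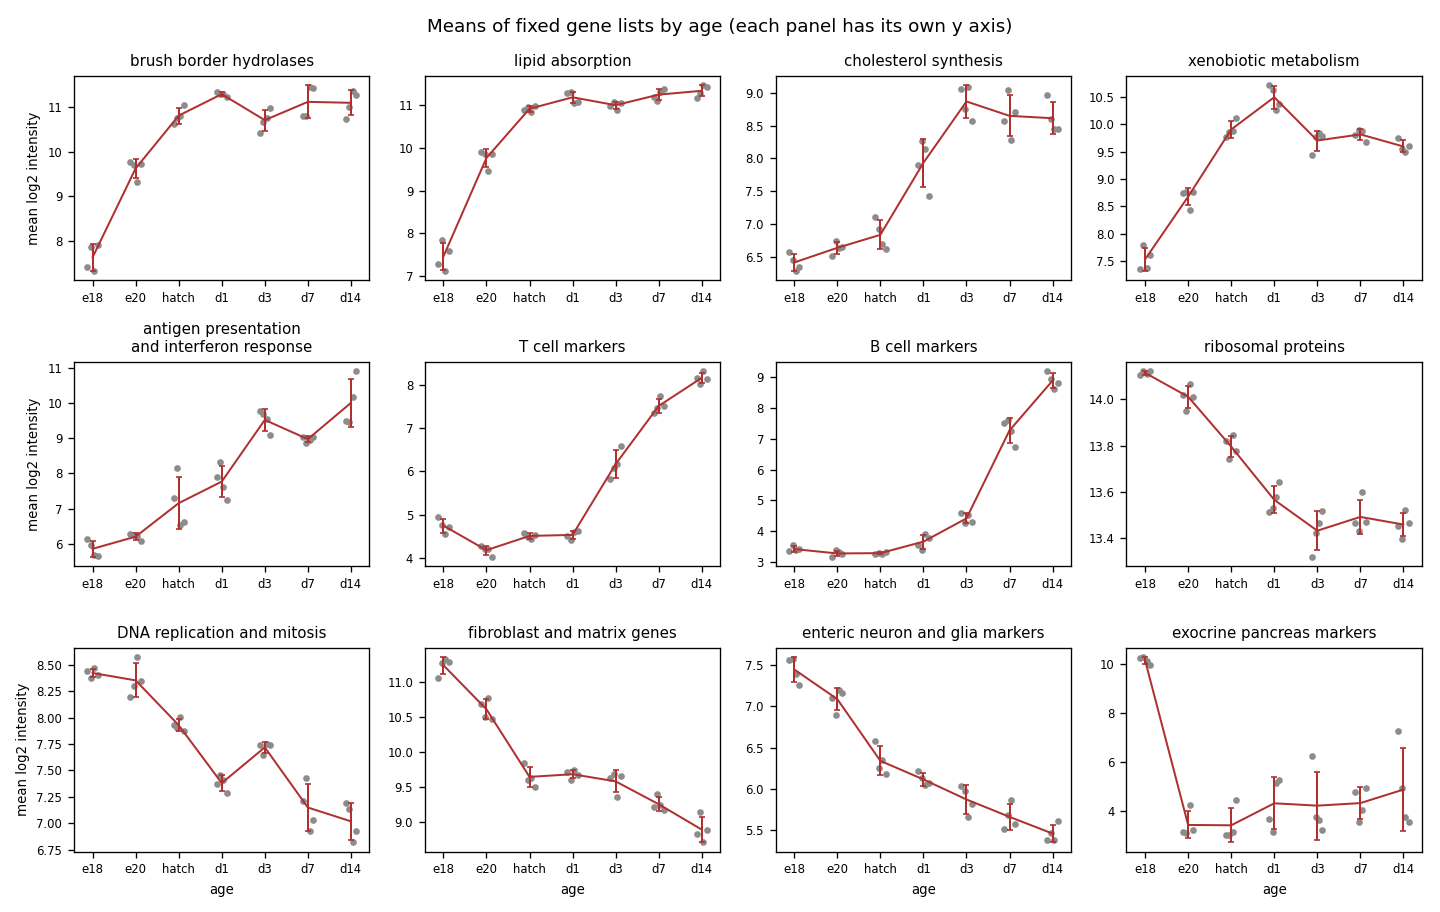
Mean log2 intensity (y axis) over the members of 12 fixed gene lists at 7 ages (x axis). Each panel has its own y axis, grey points are single arrays, and the red line joins the means of 4 arrays with bars of 1 SD. The exocrine pancreas list lies at 10.15 at e18 and at 3.44 at e20, and the T cell list goes from 4.75 at e18 to 8.16 at d14.

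The second comparison set the mean of d1 to d14 against the mean of e18 and e20. APOA4 rose by 7.75 ± 0.14, and CLCA1 and CALB1, below background at e18, were at least 308-fold and 295-fold higher after hatch, while COL14A1 changed by −5.67 ± 0.14 and UPK3BL, below background after hatch, was at least 22.4-fold lower. Among the carriers SLC10A2 was at least 47.7-fold higher, SLC51B at least 21.6-fold and SLC5A12 at least 19.4-fold. Limma called 6669 genes, 2867 higher and 3802 lower after hatch, a majority that turned to 5470 and 4303 with no filter, and 134 solute carriers, 102 higher and 32 lower (134 adjusted over the list alone). Of the called carriers 76.1% were higher, against 42.3% of other called genes (Fisher's exact test, adjusted p = 4.61e-14). With e20 alone as the age before hatch, chosen after seeing the data, 5766 genes and 114 solute carriers (78 higher, 36 lower) were called. Of the 32 lists 23 were called and 6 with an estimated correlation.

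From e18 to e20 lipid absorption and brush border genes rose while pancreas and macrophage and heterophil genes fell. SLC26A6 rose by 4.70 ± 0.32, SLC28A2 by 4.56 ± 0.15, SLC9A2 by 3.33 ± 0.19, SLC5A1 by 2.37 ± 0.12 and SLC15A1 by 2.09 ± 0.19, whereas SLC2A5 changed by −1.62 ± 0.26. LEAP2, an antimicrobial peptide, was at least 73.4-fold higher at e20 and CUBN, a receptor for vitamin uptake, at least 72.7-fold. Of 19 lipid absorption genes 16 rose and 1 fell (adjusted p = 3.44e-08, and adjusted p = 0.0829 with an estimated correlation), and of 17 brush border hydrolases 13 rose and 1 fell (adjusted p = 5.07e-06, and adjusted p = 0.133 with an estimated correlation). Of 62 respiratory chain genes 48 rose and 1 fell, 50 and 1 adjusted over the list alone (adjusted p = 2.01e-09, and adjusted p = 0.194 with an estimated correlation). Of the 10 pancreas markers 8 fell and 0 rose (adjusted p = 2.27e-06, and adjusted p = 0.133 with an estimated correlation), CTRC at −10.34 ± 1.32, with 1 e20 array at 7.95 and the others at 3.05 or below, and SYCN at least 1506-fold lower. Of 13 macrophage and heterophil markers 8 fell and 0 rose (adjusted p = 0.000412, and adjusted p = 0.149 with an estimated correlation), and the globins HBA1 and HBAD changed by −4.04 ± 0.36 and −4.70 ± 0.38 in the same step.

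Limma called 4549 genes in this step, 2449 higher and 2100 lower at e20, a majority that turned to 2145 and 2414 with centring, to 1958 and 2314 with the mean over probe sets and to 621 and 636 with a minimum change of 1. It called 100 solute carriers, 80 higher and 20 lower (101 adjusted over the list alone). Of the called carriers 80.0% were higher, against 53.2% of other called genes (Fisher's exact test, adjusted p = 7.46e-08). Of the 32 lists 20 were called and 0 with an estimated correlation.

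From e20 to hatch further carriers rose. SLC5A12 rose by 4.50 ± 0.47, SLC51B by 4.11 ± 0.45, SLC10A2 by 3.71 ± 0.35, SLC2A5 by 2.77 ± 0.26, SLC2A2 by 2.75 ± 0.31 and SLC6A19 by 2.15 ± 0.28. CALB1 rose by 5.16 ± 0.44, and COL14A1 changed by −2.46 ± 0.22. Of 27 xenobiotic metabolism genes 20 rose and 0 fell (adjusted p = 3.62e-10, and adjusted p = 0.0318 with an estimated correlation). Of 22 fibroblast and matrix genes 21 fell and 0 rose (adjusted p = 7.12e-12, and adjusted p = 0.0665 with an estimated correlation). Limma called 3632 genes, 1612 higher and 2020 lower at hatch, a majority that turned to 1810 and 1482 with the mean over probe sets and to 428 and 217 with a minimum change of 1, and 91 solute carriers, 71 higher and 20 lower (95 adjusted over the list alone). Here the share called was larger among solute carriers, 54.8%, than among other genes, 43.0% (Fisher's exact test, adjusted p = 0.0234). Of the called carriers 78.0% were higher, against 43.5% of other called genes (adjusted p = 1.27e-10).

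From hatch to d1 cholesterol synthesis genes rose and replication genes fell. The cytochrome CYP1A2 (gene ID 396051) rose by 5.75 ± 0.62 to 12.02, its highest mean over the ages, and CYP1A1 by 5.20 ± 0.49 to 9.52. SLC15A1 rose by 1.03 ± 0.19 and SLC5A1 by 0.73 ± 0.12, while SLC25A39 changed by −1.87 ± 0.18 and SLC2A9 by −1.71 ± 0.25. Of 27 xenobiotic metabolism genes 7 rose and 1 fell (adjusted p = 0.0111, and adjusted p = 0.476 with an estimated correlation). Of 14 cholesterol synthesis genes 12 rose and 1 fell (adjusted p = 7.56e-08, and adjusted p = 0.353 with an estimated correlation). Of 46 replication genes 27 fell and 0 rose, 30 adjusted over the list alone (adjusted p = 1.55e-07, and adjusted p = 0.476 with an estimated correlation). Limma called 2959 genes, 1051 higher and 1908 lower at d1, a split that moved to 1481 and 1526 with quantile normalization to 1473 and 1516 with arrays centred on the median and to 1966 and 1913 with no filter. It called 50 solute carriers, 27 higher and 23 lower (46 adjusted over the list alone), or 38 and 17 with quantile normalization, 36 and 17 with centring and 56 and 22 with no filter, and the majority turned to 16 and 34 with the mean over probe sets. Of the called carriers 54.0% were higher, against 35.2% of other called genes (Fisher's exact test, adjusted p = 0.00839).

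From d1 to d3 antigen presentation and T cell genes rose. LYG2, a lysozyme, was at least 80.7-fold higher at d3 and GZMA at least 42.8-fold, while GAMT, the last enzyme of creatine synthesis, changed by −3.43 ± 0.18 and the defensin AvBD10 was at least 6.89-fold lower. SLC22A3, an organic cation carrier, rose by 2.63 ± 0.44 and SLC10A2 by 1.28 ± 0.35, and SLC22A13 changed by −1.90 ± 0.36. Of 20 antigen presentation and interferon genes 18 rose and 0 fell, 19 adjusted over the list alone (adjusted p = 7.93e-12, and adjusted p = 0.0841 with an estimated correlation). Of 10 T cell markers 7 rose and 0 fell (adjusted p = 7.03e-08, and adjusted p = 0.0516 with an estimated correlation). The globins HBA1 and HBAD rose by 2.53 ± 0.36 and 2.32 ± 0.38 in the same step. Of 27 xenobiotic genes 14 fell and 0 rose, 17 adjusted over the list alone (adjusted p = 1.79e-07, and adjusted p = 0.081 with an estimated correlation). Limma called 2160 genes, 1263 higher and 897 lower at d3, a split that moved to 1039 and 1180 with quantile normalization and to 1022 and 1209 with centring. It called 49 solute carriers, 18 higher and 31 lower (51 adjusted over the list alone), and 36.7% of the called carriers were higher, against 59.0% of other called genes (Fisher's exact test, adjusted p = 0.00413).

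From d3 to d7 T cell and B cell genes rose and replication genes fell. IGLL1 was at least 34.5-fold higher at d7, JCHAIN at least 18.7-fold, and PIGR rose by 3.16 ± 0.34. NOXO1 changed by −3.98 ± 0.68. SLC51B changed by −1.75 ± 0.45, and SLC7A3 by −1.61 ± 0.35, while SLC2A5 rose by 0.96 ± 0.26. Of 10 T cell markers 8 rose and 0 fell, 9 adjusted over the list alone (adjusted p = 4.03e-15), and of 5 B cell markers 4 rose and 0 fell (adjusted p = 1.31e-10), and both lists passed with an estimated correlation. HBAD rose by 1.23 ± 0.38 in the same step, and HBA1, at 1.05, was not called. Of 46 replication genes 32 fell and 0 rose, 34 adjusted over the list alone (adjusted p = 9.85e-18, and adjusted p = 0.0865 with an estimated correlation). Limma called 1130 genes, 426 higher and 704 lower at d7, or 522 and 529 with centring and 103 and 52 with a minimum change of 1, and 23 solute carriers, 8 higher and 15 lower (23 adjusted over the list alone), or 9 and 11 with centring and 10 and 9 with the mean over probe sets. Without d3 replicate 1 the counts were 580 and 11, without d7 replicate 3 561 and 11 and without d7 replicate 4 650 and 14, and without d3 replicate 2 the solute carriers numbered 14.

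From d7 to d14 JCHAIN rose by 3.81 ± 0.26, IGLL1 by 3.53 ± 0.27 and CMPK2, an interferon-induced kinase, by 2.55 ± 0.49, while CYP1A1 changed by −2.35 ± 0.49 and HBAD by −1.76 ± 0.38. Of 10 T cell markers 2 rose, 8 adjusted over the list alone (adjusted p = 5.72e-11), of 5 B cell markers 2 rose (adjusted p = 6.48e-09), and of 20 antigen presentation and interferon genes 3 rose, 14 adjusted over the list alone (adjusted p = 9.71e-18). These 3 lists passed with an estimated correlation. Of 22 matrix genes 3 fell, 13 adjusted over the list alone (adjusted p = 6.97e-13, and adjusted p = 0.098 with an estimated correlation), and of 16 smooth muscle markers 0 were called, 11 adjusted over the list alone (adjusted p = 8.52e-11, and adjusted p = 0.16 with an estimated correlation). Limma called 72 genes, 34 higher and 38 lower at d14, with 879 at an unadjusted p under 0.05, and 0 solute carriers, with 14 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The majority turned to 46 and 34 with no filter, to 52 and 37 with values under 4 raised to 4, to 45 and 31 with the mean over probe sets and to 17 and 8 with a minimum change of 1, and in 6 of the fits that left out an array. The count of 72 became 43 without d7 replicate 1, 34 without d7 replicate 2 and 117 without d14 replicate 2, and was 0 with only the arrays of these ages in the limma fit, with 861 at an unadjusted p under 0.05. Other splits of the same arrays gave up to 495 genes.

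**Figure D4:**
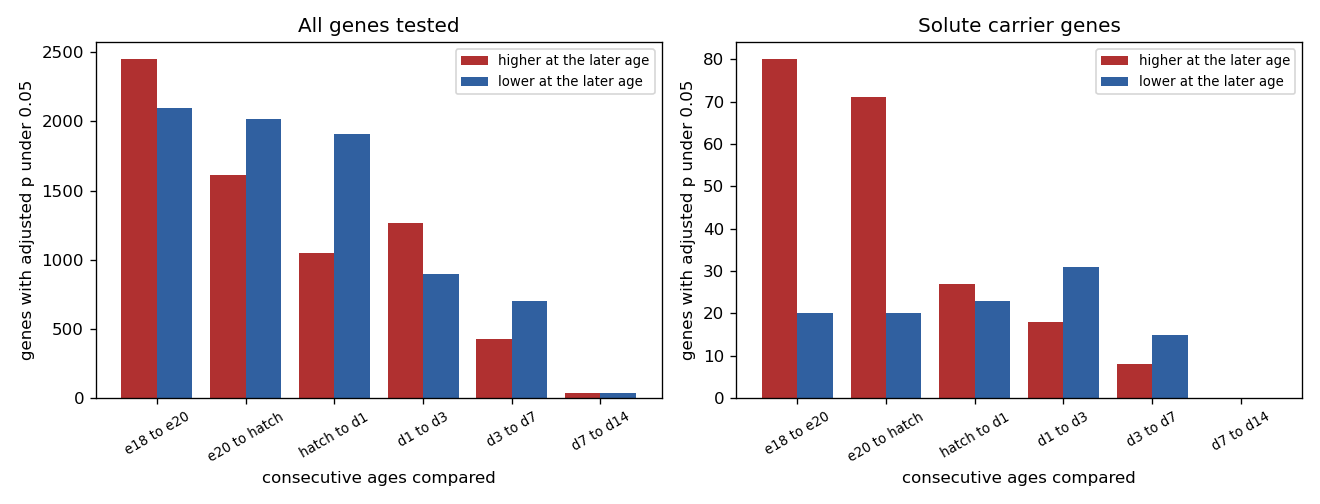
Number of genes with an adjusted p under 0.05 (y axis) in each step between consecutive ages (x axis), for all genes tested and for solute carriers. Red bars are genes higher at the later age and blue bars genes lower. Solute carrier calls fall from 100 between e18 and e20 to 0 between d7 and d14.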

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

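The tests in this part were chosen before the results were seen; which genes they would point to was not. In 462 groups of 4 arrays, 23 had an array whose gap to the nearest other, divided by the range, was over Dixon's critical value; chance gives about 1 in 20 groups, and 9 of the gaps were over 1 on the log2 scale. At e18 these arrays were, as log2 intensity, CATH1 in replicate 1 (12.21, the others at most 11.17), DPP4 in replicate 3 (4.63, the others at least 5.87), SLC5A12 in replicate 1 (2.92), GZMA in replicate 1 (2.58), LCT in replicate 2 (2.89), SREBF2 in replicate 2 (5.05), NDUFS3 in replicate 3 (5.02), PCSK1 in replicate 1 (3.01), EGFL7 in replicate 4 (7.04), SI in replicate 4 (12.30) and the mean of the goblet cell list in replicate 4 (6.49). At e20 CLCA1 was at 6.53 in replicate 1, with the others at 8.80 or above, and CTRC at 7.95 in replicate 3, with the others at 3.05 or below. At d1 ATP12A was at 5.02 in replicate 1. At d3 SLC5A12 was at 8.52 in replicate 2, with the others at 6.71 or below, NOXO1 at 7.14 in replicate 4, with the others at 8.79 or above, KRT24 at 3.14 in replicate 4 and TMEM213 at 5.19 in replicate 4. At d7 GKN2 was at 3.66 in replicate 1. At d14 CPB1 was at 7.29 in replicate 1, with the others at 2.87 or below, SLC7A3 at 3.92 in replicate 3, with the others at 5.63 or above, CYP2D6 at 11.21 in replicate 1 and SLC18A3 at 3.01 in replicate 4. The values of SLC5A12, GZMA and LCT at e18 lay below the background of that age, 3.00, with gaps of 0.486, 0.055 and 0.296. That of SLC18A3 lay below the d14 background of 3.15, with a gap of 0.107. GCRMA values are nearly constant at such levels. The arrays named for CPB1 and CTRC also had the highest mean of the exocrine pancreas list at their age. It was 7.25 in d14 replicate 1, the others at most 4.94, and 4.27 in e20 replicate 3, the others at most 3.23. These gaps are thus not confined to a single gene.

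Probe sets with no listed gene entered no comparison above. Of 10496 such probe sets 2557 passed the filter, and 2191 of these were called across ages by the same F-test.

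Other splits of the same arrays into groups of the same sizes were counted for each number of calls. For the F-test over all ages, 1 of 100 splits, the real one, gave as many calls: 7561 genes against at most 1037 in the others, and 151 solute carriers against at most 24. For d14 against e18, 1 of 35 splits gave as many, 6189 genes against at most 400 and 129 solute carriers against at most 5. For after against before hatch it was 1 of 100, 6669 genes against at most 20 and 134 solute carriers against at most 0. In the steps 1 of 35 splits gave as many in each case, from e18 to e20 4549 genes (at most 1255) and 100 solute carriers (at most 38), from e20 to hatch 3632 (28) and 91 (2), from hatch to d1 2959 (13) and 50 (1), from d1 to d3 2160 (132) and 49 (2), and from d3 to d7 1130 (344) and 23 (7). For each of these counts no other split gave as many, and 1 of 35 or 1 of 100 is the smallest result possible. These results were not adjusted for the number of counts made. The splits also treat arrays as interchangeable, although those numbered 1 and 2 differed from those numbered 3 and 4, as described among the other observations. Chance is thus less likely for each count taken singly, but is not excluded. For the 23 gene lists called between e18 and d14 chance could not be excluded either, since 3 of 35 splits gave as many and the highest other gave 24. Nor was it excluded for the 72 genes called from d7 to d14, where 2 of 35 splits gave as many, the real one and one with 495, in a count that takes no account of differences between arrays that recur across ages. For the 0 solute carriers of that step the count of splits decides nothing, since all 35 give at least 0, the highest other 13. The split with 495 genes joined replicates 1 and 2 of d7 with replicates 1 and 2 of d14, and calling several times the real count it follows the shared direction described among the other observations and points to a structure of the samples that the labels do not give and for which the fit has no term.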

How the results depend on the processing

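The settings with e20 in place of e18, without e18 and without 4 symbols that encode no carrier were chosen only after the results were seen. Counts of calls stayed within 1.5 times their main value under the other settings, with these exceptions. A minimum change of 1 on the log2 scale left 3051 genes and 83 solute carriers for d14 against e18, 2168 and 69 for after against before hatch, and in the steps in order 1257 and 55, 645 and 35, 345 and 10, 397 and 17, 155 and 2, and 25 genes, fewer by construction. With no filter, more genes being tested, 232 solute carriers were called across ages, 220 after against before hatch and 78 from hatch to d1. With log2 over 6, 38 genes were called from d7 to d14, and quantile normalization called 1 solute carrier there. With only the arrays of the ages compared, a smaller fit, 482 genes and 10 solute carriers were called from d3 to d7 and 0 genes from d7 to d14 (limma, 861 at an unadjusted p under 0.05). With an estimated correlation 7 of 23 lists were called, and with fry 30. Without e18, 25 solute carriers had their highest mean at e20. The respiratory chain list, called with either age, reversed to −0.27 with e20 in place of e18 (list respiratory chain, median log2 change). The median of the exocrine pancreas list also turned positive, at 1.22, but that list was not called with e20. Leaving out each array in turn gave 561 to 1353 genes and 11 to 24 solute carriers from d3 to d7, 34 to 117 genes and 0 to 1 solute carriers from d7 to d14; the cause was not tested. The other ranges were 7477 to 7546 genes and 148 to 152 solute carriers across ages, 6002 to 6053 and 123 to 131 for d14 against e18, 6537 to 6653 and 131 to 135 for after against before hatch, 4145 to 4437 and 95 to 100 from e18 to e20, 3095 to 3530 and 79 to 89 from e20 to hatch, 2544 to 2835 and 44 to 49 from hatch to d1, 1622 to 2093 and 36 to 47 from d1 to d3, and 22 to 23 lists. Of 165 genes named by the rule, tested for d14 against e18, 4 lost their call in some setting (NDUFS3, ALB, UQCRQ and CA2), 1 gained it (A2M) and 0 reversed. No paired fit was made because the labels pair no arrays across ages, and none was blocked by the side of the arrays on the shared direction within ages, which only record order and the values define. That difference therefore stays in the spread of every fit. Few calls in a step, as from d7 to d14, do not show that few genes changed. Signal over background limits the lowest genes, whose changes are bounds.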

Other observations

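The tests of pancreas tissue at e18, of array-wide scaling and of blood, and for the shared direction the left-out ages and the correlations within each side, were chosen only after the results were seen. Creatine genes, grouped here after their values were seen, moved in opposite directions. GATM, the first enzyme of creatine synthesis, had a mean of 8.28 ± 0.55 at e18 (SD, n = 4 arrays) and was below background at d14, at least 35.1-fold lower (limma adjusted p = 7.51e-15), with steps of −2.20 from hatch to d1 and −1.07 from d1 to d3. GAMT, the next enzyme, stood between 7.20 and 9.01 up to d1 and at 3.77 at d3. SLC6A8, which carries creatine into cells, rose by 2.23 ± 0.17, of which 1.66 came between e18 and e20.

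Globin and lysozyme transcripts, also picked after their values were seen, were high at e18, lower at e20 and higher again at d3. They were not alone in this. The macrophage and heterophil list, which holds LYG2, had means of 6.90 at e18, 4.70 at e20, 4.75 at d1, 6.26 at d3 and 7.34 at d14. HBA1 had means of 13.19 at e18, 9.15 at e20, 7.31 at hatch, 9.01 at d1, 11.54 at d3, 12.60 at d7 and 11.20 at d14; bird red cells are nucleated, and globin RNA marks blood in a sample. Limma called its fall to hatch (−4.04 and −1.84) and its rise to d3 (1.70 and 2.53), and not the steps after d3. LYG2 had a mean of 10.74 at e18, 2.55 at e20, 3.30 at d1 and 9.79 at d3, so that d14 and e18 differed by −0.33 (adjusted p = 0.279).

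Pancreas genes stood high at e18, with CTRC at 14.35, AMY2A at 13.55 and the hormone INS at 8.90, and lower from e20, though AMY2A went from 4.28 at e20 to 8.45 ± 2.37 at d14 (SD, n = 4 arrays). The median change of all 8396 genes from e18 to e20 was 0.0419, so the deposited e18 values were not shifted as a whole. Median intensities lay close together in all arrays, between 7.39 and 8.00. A difference of scale evened out before deposit could not have shown in this test. Of the 10 list genes 7 had all 4 e18 arrays above all 24 others, against 1177 of 8396 over all genes, which restates the pattern and lends no support to one explanation over another. Pancreas tissue collected with the intestine at e18 and expression in the embryonic intestine itself would both give this count. The count cannot tell them apart, and the second is a difference of age that the design names. The list mean lay between 9.96 and 10.26 in the 4 e18 arrays. Single members could differ more there, PRSS2 from 9.78 to 13.22 and CEL from 7.40 to 10.24, while CTRC stayed between 14.14 and 14.48. After e18 the list mean differed more between arrays of one age, from 3.56 to 7.25 at d14, and the cause of this was not tested. No gene of this list is in another list.

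Granule genes of heterophils, the avian counterpart of neutrophils, were also high at e18. The 4 genes CATH1, AvBD1, AvBD7 and LECT2 fell by at least 8.25 on average from e18 to d7, with 2 of them at background at d7, while HBA1 fell by 0.60. The excess was at least 7.65 (SD 0.74 between single arrays). The 4 genes were picked after their fall was seen, so a large excess was bound to follow and is no independent test. It shows only that these 4 genes did not keep the ratio to HBA1 that blood of one composition at both ages would give. Blood or tissue richer in granulocytes at e18, and expression by other cells at that age, were not tested.

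Arrays of one age differed along a shared direction: estimated at e18, hatch, d3 and d14, the direction took a share of 0.184 of the deviations at e20, d1 and d7, above the highest of 99 shuffled directions, 0.000321, but under the 0.2 set beforehand for a difference that recurs across ages and above the 0.05 set against it, so that this test left it undecided. With each age left out in turn, the direction from the other ages gave the arrays numbered 1 and 2 in record order scores from −12.3 to −6.05 and those numbered 3 and 4 from 5.99 to 13.3 at all 7 ages, so a difference of this kind recurs, and the leading direction held 27.0% of the within-age variance, the next 8.54%. A varying amount of pancreas tissue is argued against as what parts the sides: over the 24 arrays after e18 Pearson's r of pancreas genes and score was −0.129 (permutation p = 0.612) and Spearman's rho −0.107 (permutation p = 0.667), and r was 0.208 without the 2 farthest arrays (3 relations, 100000 permutations). Since the scores form separate sides, r was also computed within each: among the 12 arrays below 0 it was −0.606 (permutation p = 0.0334, adjusted p = 0.100; rho −0.343, permutation p = 0.279), which rests on 2 arrays (−0.048 without them), and among the 12 above 0 −0.246 (permutation p = 0.434, adjusted p = 0.612; rho −0.217, permutation p = 0.498; −0.391 without the 2 farthest). The lines and pools named in the design, and batches of processing, could not be tested because no label assigns them to arrays.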
